A study of Arabidopsis thaliana with 20 samples.

How the data were processed

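Chromatin-associated RNA of 10-day-old Arabidopsis seedlings had been profiled by m6A immunoprecipitation and sequencing in 5 genotypes, with 2 immunoprecipitated (IP) and 2 input libraries each. The libraries were grouped by the genotype and the library type that the labels give. Both tables hold columns of these 20 libraries and 0 columns of other samples. What separates the 2 libraries of a group is not stated. The p-values then measure only the spread between these samples, which may be technical.

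The expression table, from the input libraries, holds a deposited signal per gene, transposable element or spike-in. It has no value of 0. Of 92 spike-in rows, 45 are ERCC controls, 45 give these a second time, and 2 are an m6A and an unmodified spike-in. The sum of the 45 ERCC controls is nearly equal in all columns (109313 to 110569), while the m6A spike-in runs from 79342 to 98473 and the unmodified one from 231200 to 252640. The values therefore look scaled to the ERCC sum, and are neither raw counts nor scaled to library size. The m6A table, from the IP libraries, holds a deposited ratio per peak, scaled so that the m6A spike-in has the same value, 10.579, in every library; 37 values are 0. The labels do not state the denominator of the ratio, how peaks were merged or selected, or whether replicates were pooled for peak calling. The submitters' processing notes name fastp, HISAT2, SAMtools, Picard, MACS2, featureCounts and bedtools, without versions, and the genome build TAIR10. Because the values are not counts, depth is unknown and no counting interval could be given.

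Spike-in features were set aside, which left 2291 peaks and 30613 expression features. Peaks were assigned to a gene of a TAIR10.1 gene table when they overlapped exactly 1 gene by at least 50% of the peak's length. A total of 26417 expression features matched the gene table. Organelle-encoded genes were recognised by their identifiers.

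The design below was fixed before the data were examined. Values were analysed as log2(value + pseudocount), where the pseudocount was the 5th percentile of the non-zero values (0.54159 for m6A, 6.9386 for expression). Features had to reach the pseudocount in at least 2 libraries, which removed none. For each table limma (3.58.1, in R 4.3.3) fitted 5 group means to the 10 libraries with a trend in the prior variance, without further scaling. It tested 9 contrasts, two-sided: each active form against its inactive form, del-cIDR against FL, each line against Col-0, the difference between the 2 activity effects (interaction), and active against inactive over both forms. A feature was called at a Benjamini-Hochberg adjusted p under 0.05 over all features of the table. Library medians of the 4 active and 6 other libraries were compared with an exact permutation test. It permutes single libraries, while activity belongs to a line, so its p does not measure the spread between lines. The 2 activity effects were correlated across peaks. After seeing the data, photosynthesis peaks were also compared with other peaks of the lowest of 10 level classes, with the level taken from groups outside the contrast, by permutation tests over peaks adjusted over the 9 contrasts. Where the level came from Col-0, 13 of the 14 photosynthesis peaks lay in that class and were compared. The expression change of genes with and without a called peak, 1 peak per gene, was compared with a permutation test by random draws, whose smallest possible p was 1e-05, in a family of 32 tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.

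Gene lists written in advance covered m6A writers, erasers and readers, nuclear photosynthesis, heat response, cold and ABA response, salicylic acid and immune response, jasmonate and wounding, circadian clock, flowering time, DNA methylation and silencing, histone methylation, root hair and root uptake, root endodermis, xylem, phloem, guard cell, shoot epidermis, seed storage, dividing cells, plastid-encoded, mitochondria-encoded and nuclear-encoded ribosomal protein genes. Lists with at least 3 tested members were compared with all other features by camera with a preset correlation of 0.01, adjusted over the lists of a contrast. An estimated correlation, fry, and camera after median-centring were alternatives. Several lists respond to the same stimuli and share regulation, so their tests are not independent.

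Genes were named by a rule. For del-cIDR and FL each against its inactive form and against Col-0, and for del-cIDR against FL, these were the 12 features of largest fold change in each direction, in each table. They had to be called, with libraries of the groups not overlapping, and with a mean at or above the median of all features. Where fewer than 5 passed in a direction, the 5 of smallest p are also given and said not to pass. All members of the m6A machinery lists and the 4 members of smallest p of each other list were added, of which the text prints a part.

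The alternatives were no filter, a stricter filter (mean over the 10 libraries at or above the median of the table), pseudocounts 10 times larger and smaller, median-centring, quantile normalization, a replicate block, only the libraries of the groups compared, no trend and robust moderation of the variance, a log2 fold change of at least 1, leaving out organelle-encoded genes, and leaving out each library in turn. Floor alignment, which subtracts from each library the excess of its 5th percentile over the lowest among the libraries, was added after seeing the data. Where leaving out a library left a group with 1 library, that library was assumed to vary like the other groups.

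The pipeline was tested on simulated data of the same size in which 200 features differed between del-cIDR and inactive del-cIDR. In m6A it recovered 0 of 67 features changed by a log2 of 0.5, 5 of 67 changed by 1 and 32 of 66 changed by 2, and in expression 14 of 67, 37 of 67 and 61 of 66, with 2 false calls in each table. When whole libraries were shifted at random, by an SD of 0.41 in m6A and 0.09 in expression, del-cIDR against Col-0 gave a median of 0 calls over 20 draws, with at most 41 and 17.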

Results

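The libraries came from chromatin-associated RNA of 10-day-old whole Arabidopsis seedlings, profiled by MeRIP-seq, in which an antibody enriches RNA fragments that carry N6-methyladenosine (m6A). There were 5 genotypes: untransformed Col-0, and lines that overexpress human ALKBH5, an m6A demethylase, as full length (FL), as full length with an inactivated catalytic site (inactive FL), without the C-terminal intrinsically disordered region (del-cIDR), or without that region and with the inactivated site (inactive del-cIDR). Each genotype had 2 immunoprecipitated (IP) and 2 input libraries, 20 libraries in all. The m6A table held 2291 peaks, of which 2247 lay on nuclear chromosomes, 23 on the plastid genome and 21 on the mitochondrial genome. The expression table held 30613 features, among them 22841 protein-coding genes and 4050 transposable elements. Because the values are scaled, the sequencing depth of the libraries is unknown and no counting interval is given. Values below are means ± SD of the 2 libraries of a group (n = 2), and fold changes are on the log2 scale.

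Peaks sat near an end of their gene. Position was counted by coordinate without regard to strand, so the start and the end of a transcript are not told apart. The first block of the table, 1300 peaks, had a median relative position of 9.4% of the gene from its lower coordinate, and 83.3% of its assigned peaks lay in the first 20% of the gene. In the second block, 991 peaks, the median was 90.8% and 82.9% lay in the last 20%. The labels name TAIR10 and the gene table used here is of TAIR10.1, so small differences between annotations cannot be seen. By position 95% of nuclear peaks overlapped a gene, against 65.8% to 81.5% after shifts of 500 to 20000 bases. In total 2028 peaks fell in 1 gene, 107 in 2 or more and 112 nuclear peaks in none, and 1981 genes carried a peak.

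All 4 ALKBH5 lines had lower m6A values than Col-0. The median peak value was 6.84 ± 0.346 in Col-0, 3.42 ± 1.69 in FL, 3.30 ± 0.461 in inactive FL, 2.15 ± 0.674 in del-cIDR and 3.54 ± 1.45 in inactive del-cIDR. Nuclear peaks fell from 6.91 ± 0.328 in Col-0 to 2.19 ± 0.706 in del-cIDR, plastid peaks from 3.04 to 0.708, and mitochondrial peaks from 3.40 to 0.291. In the other lines plastid peaks had 1.13 in FL, 0.774 in inactive FL and 0.680 in inactive del-cIDR, and mitochondrial peaks 0.784, 0.430 and 0.385. The comparison fixed in advance, the 4 active IP libraries against the 6 others, differed by -0.61 in log2 median (exact permutation test, two-sided p = 0.133 over 210 assignments). Added after the values were seen, the 8 transgenic libraries against the 2 of Col-0 differed by -1.07 (exact permutation p = 0.0222, the smallest that 45 assignments allow). The 4 active against the 4 inactive libraries differed by -0.30 (exact permutation p = 0.4 over 70 assignments). Single libraries were permuted, so these p-values do not measure the spread between lines. FL replicates stood apart, at 2.23 and 4.62, as did inactive del-cIDR replicates, at 2.51 and 4.57. Without FL replicate 2 the fixed comparison gave -0.84 (exact permutation p = 0.0476). No other single library left out brought its p under 0.05, and without del-cIDR replicate 2 it gave -0.43 (exact permutation p = 0.31).

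**Figure D1:**
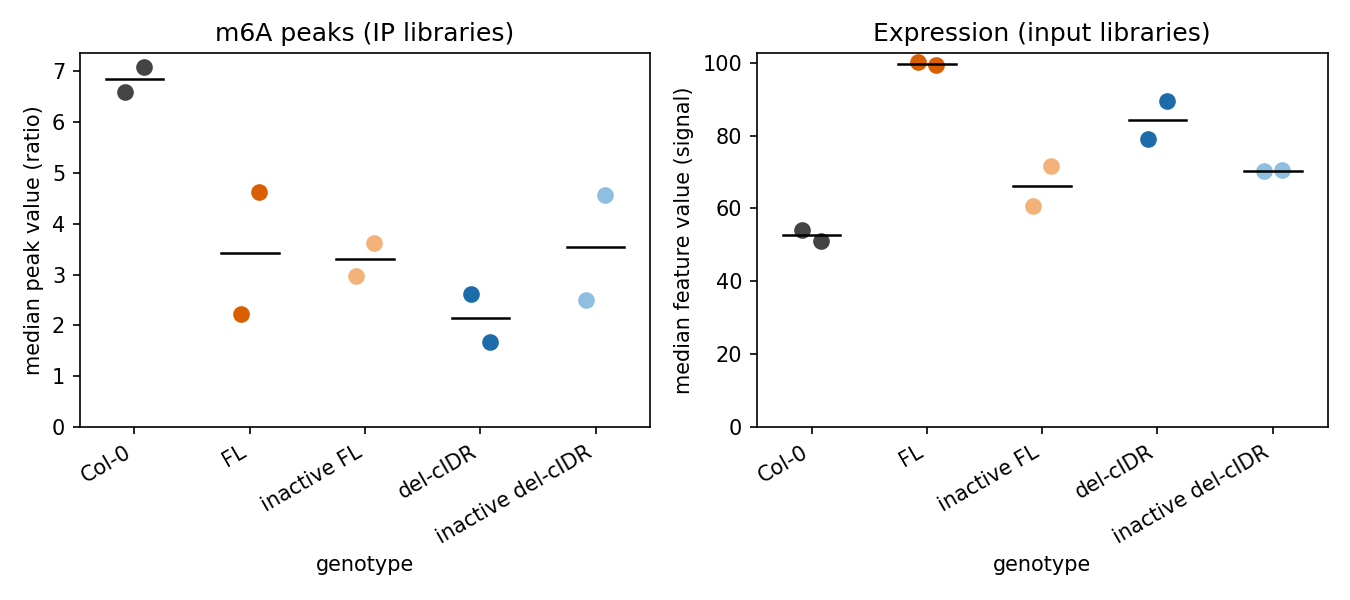
Median value per library of the m6A peaks (left, ratio) and of the expression features (right, signal), by genotype; points are libraries and lines are the means of 2 libraries. The 2 Col-0 libraries have the highest m6A medians, 6.60 and 7.09, and the lowest expression medians, 54.2 and 51.0.

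Photosynthesis transcripts had peaks of low level, which fell against Col-0 in all 4 lines. All 14 peaks on nuclear photosynthesis genes passed the test in each of the 4 lines, 14 of 14 lower. The peak on PSAF, a subunit of photosystem I (chromosome 1, 11215745 to 11216069), had 4.19 ± 0.0239 in Col-0, 0.677 ± 0.172 in FL, 0.333 ± 0.110 in inactive FL, 0.257 ± 0.0689 in del-cIDR and 0.430 ± 0.265 in inactive del-cIDR. On RBCS3B, a small subunit of Rubisco (chromosome 5, 15378162 to 15378388), the value was 3.0 ± 0.207 in Col-0, 0.561 in FL and 0.134 ± 0.00643 in del-cIDR. Against peaks of all levels the list was lower in FL (median -1.70, camera adjusted p = 1.1e-25), del-cIDR (-2.30, 9e-27), inactive FL (-2.07, 3.96e-29) and inactive del-cIDR (-2.10, 6.61e-27). With an estimated correlation these calls were lost: the adjusted p was 0.107 for FL, 0.0986 for del-cIDR, 0.0834 for inactive FL and 0.0976 for inactive del-cIDR. By a comparison added after the values were seen, all 14 lay in the lowest of 10 classes of peak level, taken from the groups of the other activity. The 216 other peaks of that class had medians of -1.50 in FL, -2.14 in del-cIDR, -1.87 in inactive FL and -1.98 in inactive del-cIDR. The list was lower than these by 0.20 in FL, 0.15 in del-cIDR, 0.20 in inactive FL and 0.12 in inactive del-cIDR, and no difference passed (permutation tests over peaks, adjusted p = 0.5 for each over 9 contrasts).

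**Figure D2:**
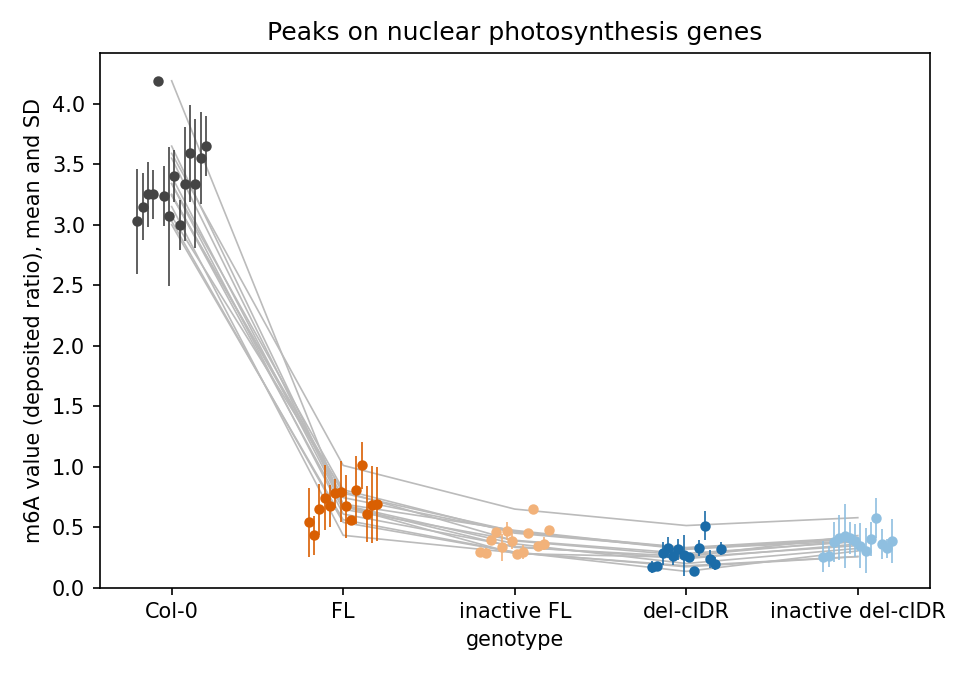
m6A values (ratio) of the 14 peaks on nuclear photosynthesis genes by genotype; each point is a peak, bars are the SD of 2 libraries, and lines join a peak across genotypes. PSAF, the highest in Col-0 at 4.19, is at 0.257 in del-cIDR.

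The comparison of del-cIDR with Col-0 sets the active enzyme without its disordered region against untransformed plants. Of the peaks named by the rule, which have a mean at or above the median of all peaks, those on AT3G63340 (1.12 ± 0.410 in del-cIDR, 14.1 ± 3.25 in Col-0, log2 fold change -3.15, adjusted p = 4.22e-07) and on TAF15b, a TBP-associated factor (1.07 ± 0.444 against 12.8 ± 2.62, -3.07, 7.92e-07), fell most. The peak on DCL2, a Dicer-like ribonuclease of small-RNA pathways (chromosome 3, 768026 to 768229), fell from 8.13 ± 0.938 to 0.856 ± 0.120 (-2.63, 3.53e-05). The other peaks named by the rule lay on AT1G63855, AT2G26200, AT1G69420, ABCC8, SOL1, AT2G32340, UBC2, AT3G58510 and AT4G32820, between -3.04 and -2.49. Of the reader genes, ECT7 carried a peak that fell from 10.7 ± 1.16 to 2.2 ± 0.652 (-2.05, 0.00134), while the ECT3 peak had 3.78 ± 0.260 and 1.64 ± 0.426 (-1.0, 0.0671). Writers and the plant ALKBH9 and ALKBH10 erasers had no peak. limma called 0 peaks higher and 1829 lower (1897 at unadjusted p under 0.05). None of the 5 higher peaks of smallest p passed, of which 4 lay in no gene and 1 overlapped 2 genes. The last was at chromosome 3, 12670158 to 12670493 (12.4 ± 2.55 against 6.29 ± 1.52, adjusted p = 0.119), and the others included chromosome 2, 5799617 to 5799866 (0.299) and chromosome 4, 1483027 to 1483285 (0.818).

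Among fixed lists in the same comparison, 3 of 3 flowering-time peaks fell, on SOC1 (3.83 ± 0.473 to 0.415 ± 0.0222), FLM (14.9 ± 0.701 to 3.94 ± 1.24) and SVP (6.56 ± 0.173 to 2.55 ± 0.605). Of 3 clock-gene peaks, those on GRP7 (-2.09) and LUX (-1.85) fell, and GI had 9.95 ± 3.45 and 4.74 ± 1.28 (adjusted p = 0.102). The 2 cold-list peaks, both on COR47, fell by 2.21. Of 3 peaks on histone methylation genes, ELF6 (-2.36) and SWN (-1.27) fell and FIE did not pass (-1.08, 0.0696). All 4 peaks on ribosomal protein genes fell. Adjusted over the list alone the counts were the same for these lists. The camera test against the other peaks gave adjusted p = 0.939 for the flowering, histone and ribosomal lists, with a positive sign against negative medians for the last of these and for histone methylation, and 0.34 for the clock list. The median of all peaks moved by -1.52: relative to it DCL2 was -1.11, AT3G63340 -1.63 and ECT7 -0.54, and after median-centring 3 peaks were called. Without centring, 710 were called when only peaks of above-median mean were tested. Floor alignment, chosen after seeing the data, gave 5 higher and 37 lower. The count was 855 without Col-0 replicate 1, 724 without Col-0 replicate 2 and 622 without del-cIDR replicate 2.

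FL against Col-0, the same question for the complete enzyme, gave 0 peaks higher and 521 lower with limma (1010 at unadjusted p under 0.05, median -1.0). With the stricter filter 0 peaks were called, and with floor alignment 2 higher and 6 lower. Among the peaks named by the rule, the one on LTA3 fell most (3.61 ± 4.19 against 14.5 ± 9.13, log2 fold change -2.22, adjusted p = 0.00138). Peaks on AT4G12750 (-2.12), the kinase gene MPK20 (-2.0), the receptor kinase gene RK2 (2.48 ± 0.495 against 11.6 ± 3.31, -1.99, 0.00389), AT5G15700, AT1G58110, NUDT20, AT3G60210, AT4G17020, AT2G41020, TSL and AT2G12500 followed, down to -1.82. The ECT7 peak had 3.74 ± 1.16 (adjusted p = 0.0548) and the ECT3 peak 2.13 ± 1.19 (0.209). In the fixed lists 2 of 3 clock peaks fell (GRP7 -1.55, LUX -1.37; camera adjusted p = 0.165), 1 of 3 histone methylation peaks (ELF6, -1.71; 0.963), 1 of 4 ribosomal protein peaks (0.963) and 0 of 3 flowering peaks (0.963). Adjusted over the list alone, 1 flowering peak passed. No higher peak passed. The first of the 5 of smallest p, in no gene, was at chromosome 2, 5799617 to 5799866 (13.6 ± 11.2 against 5.18 ± 0.343, adjusted p = 0.14). The count was 196 and 199 without Col-0 replicates 1 and 2, 187 without FL replicate 1 and 1590 without FL replicate 2, and 0 after median-centring.

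Both inactive lines were also below Col-0: limma called 0 peaks higher and 500 lower in inactive FL (938 at unadjusted p under 0.05; median -0.97) and 0 higher and 551 lower in inactive del-cIDR (896; median -0.95). In inactive FL 2 clock peaks, 1 flowering, 1 histone methylation and 1 ribosomal protein peak fell (camera adjusted p = 0.357 and 0.824 for the last 3), and in inactive del-cIDR 1 peak of each (0.274 for the clock, 0.818 for histone methylation, 0.906 for the other 2). Leaving out a library gave, for inactive FL, 228 and 243 without Col-0 replicates 1 and 2, 259 and 332 without its own replicates 1 and 2, and 845 and 848 without FL replicates 1 and 2. For inactive del-cIDR it gave 275 and 271 without Col-0 replicates 1 and 2, and 270 and 886 without its own replicates 1 and 2. Both counts became 0 after median-centring and with the stricter filter.

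del-cIDR against inactive del-cIDR compares active and inactive enzyme without the disordered region, in separate transgenic lines. Few single peaks differed: limma called 0 higher and 4 lower (275 at unadjusted p under 0.05), while the median of all peaks moved by -0.51. The 4 peaks, named after their values were seen, lay at chromosome 1, 8814591 to 8816593, in no gene (0.193 ± 0.273 against 2.84 ± 2.71, log2 fold change -1.97, adjusted p = 0.00756), and at chromosome 4, 2994467 to 2994731, in no gene (0.103 ± 0.0474 against 0.834 ± 0.438, -1.06, 0.0262). Another was at chromosome 1, 28255458 to 28255773 (0.358 ± 0.227 against 2.62 ± 0.336, -1.83, 0.0367) and the last at chromosome 5, 8959229 to 8959622 (0.249 ± 0.0606 against 2.92 ± 1.61, -2.05, 0.0367). These 2 each overlapped 2 genes. In each of the 4 called peaks the del-cIDR mean lay below the pseudocount, so the size of the log2 change depends on the pseudocount. With the stricter filter, and also without a trend in the prior variance, 0 peaks were called. Under the rule for named genes, lower peaks on DCL2 (0.856 ± 0.120 against 7.11 ± 6.42, adjusted p = 0.068), AT4G15080 (0.0751), AT1G69420 (0.0781) and CALS1, a callose synthase gene (0.0971), and higher peaks on AT5G29975 (0.704 ± 0.452 against 0.0820 ± 0.116, 0.068) and AT3G47875 (0.421), did not pass. The ECT7 and ECT3 peaks did not pass either (-0.84, 0.517, and -0.91, 0.471). No member of the fixed lists passed, with camera adjusted p = 0.426 for photosynthesis, flowering and histone methylation and 0.807 for the clock and ribosomal lists. The tests for photosynthesis and the clock had a positive sign against negative medians of -0.15 and -0.19, and adjusted over the list alone 1 histone methylation peak passed. The count was 0 without Col-0 replicate 1, Col-0 replicate 2 or inactive del-cIDR replicate 2, 1 without del-cIDR replicate 2, 2 without del-cIDR replicate 1 (1 higher and 1 lower), 2 without inactive FL replicate 1, 7 without inactive del-cIDR replicate 1, and 40 and 41 without FL replicates 1 and 2. After median-centring it was 0.

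For FL against inactive FL, the complete enzyme with and without an active site in separate lines, limma called 5 peaks higher and 0 lower (82 at unadjusted p under 0.05; median -0.01). These 5, named after their values were seen, lay on AT2G05295 (1.46 ± 0.0486 against 0.141 ± 0.199, log2 fold change 1.58, adjusted p = 6.74e-09), AT1G40104 (3.96 ± 1.87 against 0.369 ± 0.323, 2.29, 0.00196) and AT4G20700 (1.49, 0.00212). The others were on the immune receptor gene SNC1 (0.548 ± 0.168 against 0.0593 ± 0.0839, 0.86, 0.00337) and, in no gene, at chromosome 5, 3252895 to 3253122 (1.79, 0.00583). In each of the 5 called peaks the inactive FL mean lay below the pseudocount, so the size of the log2 change depends on the pseudocount. With the stricter filter, and also without a trend in the prior variance, 0 peaks were called. Lower peaks did not pass, among them the peak at chromosome 1, 8814591 to 8816593 (0.873 ± 0.00251 against 3.76 ± 0.661, adjusted p = 0.0549), AT2G47020 (0.0665) and SAP130b, a splicing factor gene (0.847). The 14 photosynthesis peaks were higher as a list (median 0.38, camera adjusted p = 6.04e-09; adjusted p = 0.599 with an estimated correlation), though 0 passed singly and 217 other peaks in the lowest of 10 classes of Col-0 level had a median of 0.31 (permutation test, adjusted p = 0.5). No other list passed (clock 0.959, flowering 0.769, histone methylation 0.601, ribosomal 0.714). ECT7 and ECT3 peaks had 0.61 and 0.02 (both 0.999). The count was 11 without FL replicate 1, 16 without FL replicate 2 (7 higher and 9 lower, which turned the direction), 12 and 2 without inactive FL replicates 1 and 2, and 8 without inactive del-cIDR replicate 1 or 2. After median-centring it was 0.

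Directly between the active forms, del-cIDR against FL, limma called 0 peaks higher and 20 lower (360 at unadjusted p under 0.05; median -0.52), 18 nuclear and 2 mitochondrial. The rule named DCL2, 0.856 ± 0.120 in del-cIDR and 5.68 ± 1.59 in FL (log2 fold change -2.13, adjusted p = 0.0298), whose change relative to the median was -1.61. LDA, a limit dextrinase of starch breakdown (-1.52, 0.0562), AT2G10940 (0.0564), AT1G40104 (0.0627) and ATBCAT-5, a branched-chain aminotransferase gene (0.0739), did not pass, nor did the higher peaks on AT2G21190 (0.2), AT2G01010 (0.208), LTA3 (0.393), AT2G31710 (0.398) and AT4G12750 (0.418). Photosynthesis peaks were lower as a list (median -0.59, camera adjusted p = 1.59e-06; adjusted p = 0.77 with an estimated correlation and 0.898 after median-centring), 0 singly and 11 adjusted over the list alone. Other peaks in the lowest class of Col-0 level had a median of -0.54 (permutation test, adjusted p = 0.759). Among the others, flowering had 0.202 and the clock, histone methylation and ribosomal lists 0.955, the last pair with a positive sign against negative medians. ECT7 had -0.64 (0.593) and ECT3 -0.24 (0.818). The count was 9 and 10 without Col-0 replicates 1 and 2, 296 without FL replicate 1, 12 and 13 without inactive FL replicates 1 and 2, and 10 and 8 without del-cIDR replicates 1 and 2. After median-centring it was 0.

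Across the 2291 peaks, the log2 effect of activity in the del-cIDR form and that in the full-length form correlated weakly (Spearman 0.155, Pearson 0.147; peaks are not independent replicates). Without FL replicate 1 the Spearman value was -0.02, without inactive FL replicate 2 it was 0.052, without del-cIDR replicate 2 0.033 and without inactive del-cIDR replicate 2 0.03. Averaged over both forms, active against inactive, limma called 1 peak higher, on AT5G29975 (0.75, adjusted p = 0.0403), and 1 lower, at chromosome 1, 8814591 to 8816593 (-1.78, 6.23e-06), with 152 at unadjusted p under 0.05. Both are named after their values were seen. The photosynthesis list was higher (median 0.10, camera adjusted p = 6.48e-06; adjusted p = 0.845 with an estimated correlation), and other peaks in the lowest class of Col-0 level had a median of 0.11 (permutation test, adjusted p = 0.855). That count was 93 without FL replicate 2 (7 higher and 86 lower), 4 without inactive FL replicate 1, and 1 without Col-0 replicate 2, inactive FL replicate 2, del-cIDR replicate 2 or inactive del-cIDR replicate 2.

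In the input libraries the median feature value was higher in every ALKBH5 line than in Col-0, while the total scaled signal was not higher in all of them. Medians were 52.6 ± 2.25 in Col-0, 99.7 ± 0.667 in FL, 66.3 ± 7.73 in inactive FL, 84.3 ± 7.29 in del-cIDR and 70.4 ± 0.256 in inactive del-cIDR. Totals were 33267788 and 34382876 in Col-0, 34314312 and 33527724 in FL, 33223787 and 32502088 in inactive FL, 35109867 and 36760995 in del-cIDR, and 33590501 and 33631417 in inactive del-cIDR. The active libraries exceeded the 6 others by 0.50 in log2 median (exact permutation test, two-sided p = 0.00476, the smallest that 210 assignments allow). Added after the values were seen, the transgenic libraries exceeded Col-0 by 0.53 (exact permutation p = 0.0222, the smallest of 45 assignments). The active exceeded the inactive by 0.39 (exact permutation p = 0.0286, the smallest of 70). All of these tests permute single libraries and not lines, so the p-values do not measure the spread between lines. For each line against Col-0 the difference was larger in weakly than in strongly expressed features. FL exceeded Col-0 by a median of 1.15 in the lowest of 10 classes of Col-0 level and by 0.20 in the highest. The classes were formed from the same Col-0 values, which by itself can raise the change of the lowest class in comparisons with Col-0. In comparisons without Col-0 the pattern varied. Between FL and inactive FL the median was 0.72 in the lowest and 0.20 in the highest class. Between del-cIDR and inactive del-cIDR the median was 0.28 in the lowest and 0.33 in the highest class. Plastid-encoded transcripts took 31.0% and 30.4% of the signal in Col-0, 21.4% and 21.8% in FL, 27.2% and 26.5% in inactive FL, 32.5% and 32.3% in del-cIDR, and 36.8% and 36.7% in inactive del-cIDR. Because these medians moved, gene changes below carry a second value, called relative, which is the log2 change minus the median of all features. That median covers features of all levels, and expression lists were not compared with features of like level. Relative values and list tests can therefore in part reflect level.

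**Figure D3:**
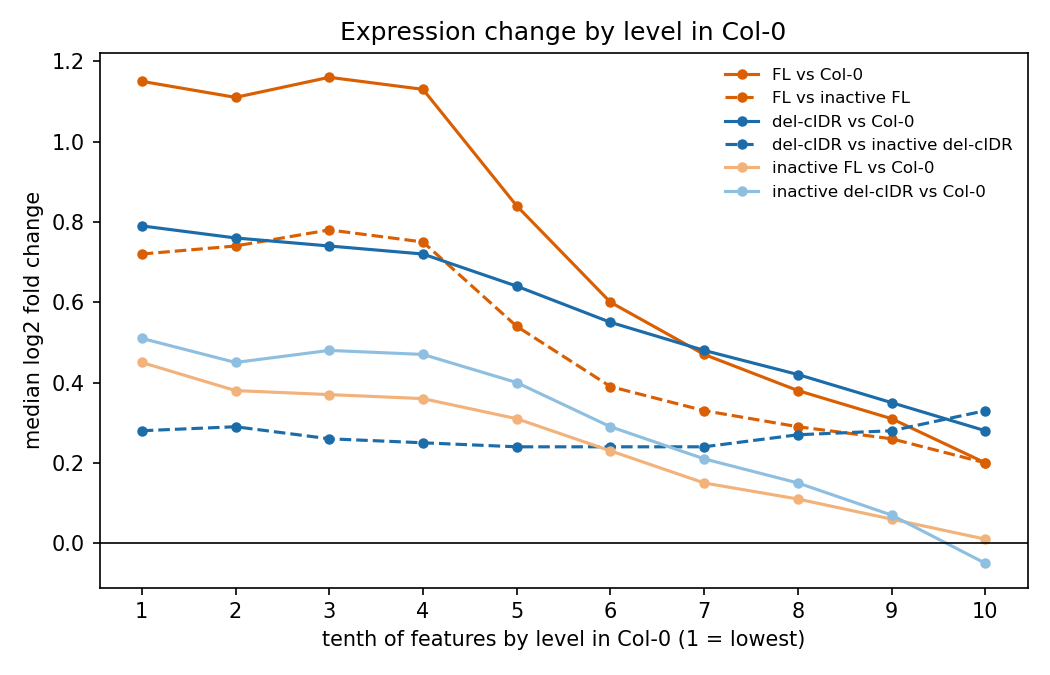
Median log2 fold change of expression against the level in Col-0, in 10 classes of about 3061 features from lowest (1) to highest (10), for 6 comparisons. FL against Col-0 falls from 1.15 to 0.20, while del-cIDR against inactive del-cIDR stays between 0.24 and 0.33 in all classes. Comparisons with Col-0 use the same Col-0 values that formed the classes.

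In del-cIDR against inactive del-cIDR, which are separate lines, most genes of the clock list were higher and most photosynthesis and jasmonate genes lower. Against Col-0, given below, most photosynthesis and jasmonate genes were higher in both lines, and most clock genes were lower in inactive del-cIDR. The difference can therefore lie in either line. COR27, a clock- and cold-regulated gene, had 934 ± 10.7 against 137 ± 4.81 (log2 fold change 2.71, relative 2.44, adjusted p = 1.26e-35). The clock gene FKF1, a blue-light receptor that promotes flowering, had 1951 ± 4.80 against 379 ± 14.3 (2.34, relative 2.08, 1.33e-34), GRP7 62397 ± 872 against 15875 ± 193 (1.97, relative 1.71, 3.61e-44), TOC1 4205 ± 10.7 against 1349 ± 39.0 (1.64, relative 1.37) and LUX 1.69 (relative 1.43). LHY and CCA1, the morning clock factors, were lower (-0.94 and -0.91). On the clock list 11 of 16 genes rose and 4 fell, also when adjusted over the list alone (median 1.17, camera adjusted p = 1.53e-10; adjusted p = 0.0921 with an estimated correlation). Other genes named by the rule as higher were AT3G57420, AT4G33980, AT1G67105, AT1G07050, AT1G17665, AT4G25580, AT5TE37665, AT5TE31020, AT5G24915 and AT5G28335, from 2.51 to 2.07. Lower were AT1G13650 (-2.64, relative -2.91), AT3G28270, the arginase gene ARGAH2 (-1.95), the chalcone synthase gene TT4 (70.0 ± 3.55 against 244 ± 24.5, -1.70), LHCB2.3, LOX2, SQP1, BBX16, ARP9, AT3G28220, VSP2 and LHCB2.2, down to -1.35.

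Of 25 nuclear photosynthesis genes in that comparison, 21 fell and 1 rose (22 and 1 adjusted over the list alone; median -0.47, relative -0.74, camera adjusted p = 1.36e-56; adjusted p = 0.0386 with an estimated correlation). RCA, the Rubisco activase, had 26089 ± 400 against 49553 ± 596 (-0.93, relative -1.19), LHCB2.2, a light-harvesting protein, 1830 ± 15.3 against 4665 ± 86.6 (-1.35, relative -1.61), and RBCS2B -1.18. On the jasmonate list 6 of 9 genes fell and 0 rose (7 and 0 over the list alone; camera adjusted p = 3.75e-17; adjusted p = 0.0285 with an estimated correlation). Biosynthesis genes were among them, LOX2 (696 ± 40.5 against 2046 ± 74.7, -1.55, relative -1.82), OPR3 (-1.01) and AOS (-0.81). On the cold and ABA list 10 of 14 rose and 2 fell (camera adjusted p = 0.0779), with RD29A at 2552 ± 92.1 against 1255 ± 19.1 (1.02, relative 0.75). KIN2 was at 1.17 and the cold transcription factor CBF1 at 0.99, while the dehydrin gene RAB18 fell (-0.48). Plastid-encoded genes rose, 90 of 132 with 12 lower (median 0.32, camera adjusted p = 2.11e-12; adjusted p = 0.328 with an estimated correlation), as did 9 of 14 mitochondria-encoded genes (0.000702; adjusted p = 0.0721 with an estimated correlation). Relative to the median both were near 0 (0.05 and 0.04), and both calls ended after median-centring (0.232 for both). Of 3 guard cell genes 2 rose and 0 fell (3 over the list alone; camera adjusted p = 0.0943). Phloem and shoot epidermis lists held 2 genes each and were not tested as lists: SUC2 had -0.18 (adjusted p = 0.0538) and APL 0.21 (0.381), and PDF1 (0.50) and ATML1 (0.39) rose.

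For the m6A machinery in del-cIDR against inactive del-cIDR, 7 of 8 writer genes rose (8 adjusted over the list alone; median 0.46, camera adjusted p = 0.00121; adjusted p = 0.124 with an estimated correlation and 0.114 after median-centring). The methyltransferase genes MTA and MTB had 0.56 (relative 0.29) and 0.37 (0.10), FIP37 0.32 (0.06), VIR 0.56 (0.30), HAKAI 0.55 (0.28), FIO1 0.74 (0.47) and HIZ2 0.35 (0.08), and HIZ1 did not pass (0.18, adjusted p = 0.0858). Of 5 plant erasers ALKBH9A (0.93), ALKBH9C (0.41) and ALKBH10B (0.34) rose, and ALKBH9B (0.14, 0.302) and ALKBH10A (0.15, 0.614) did not pass (camera adjusted p = 0.361). Among 13 readers ECT2 (6304 ± 184 against 3987 ± 15.7, 0.66, relative 0.39), ECT3 (0.63), ECT4 (0.57), ECT1 (0.38), ECT7 (0.38) and ECT10 (0.36) rose, ECT8 fell (-0.26), and ECT5, ECT6, ECT9, ECT11, ECT12 and CPSF30 did not pass, with adjusted p between 0.0703 and 0.423. In FL against inactive FL 7 writers, 4 erasers and 10 readers rose and 0 fell (camera adjusted p = 0.273, 0.675 and 0.165), and the sign of all 3 list tests turned after median-centring. In del-cIDR against Col-0 5 writers rose and 1 fell, 4 erasers rose, and 6 readers rose and 2 fell (camera adjusted p = 0.949, 0.918 and 0.0227, the last negative against a median of 0.24 and 0.461 with an estimated correlation); the tests of the first pair turned negative after median-centring (0.0652 and 0.791).

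Across the whole table limma called 8782 features higher and 844 lower in del-cIDR than in inactive del-cIDR, and 2567 and 2141 after median-centring (median of all features 0.27).

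**Figure D4:**
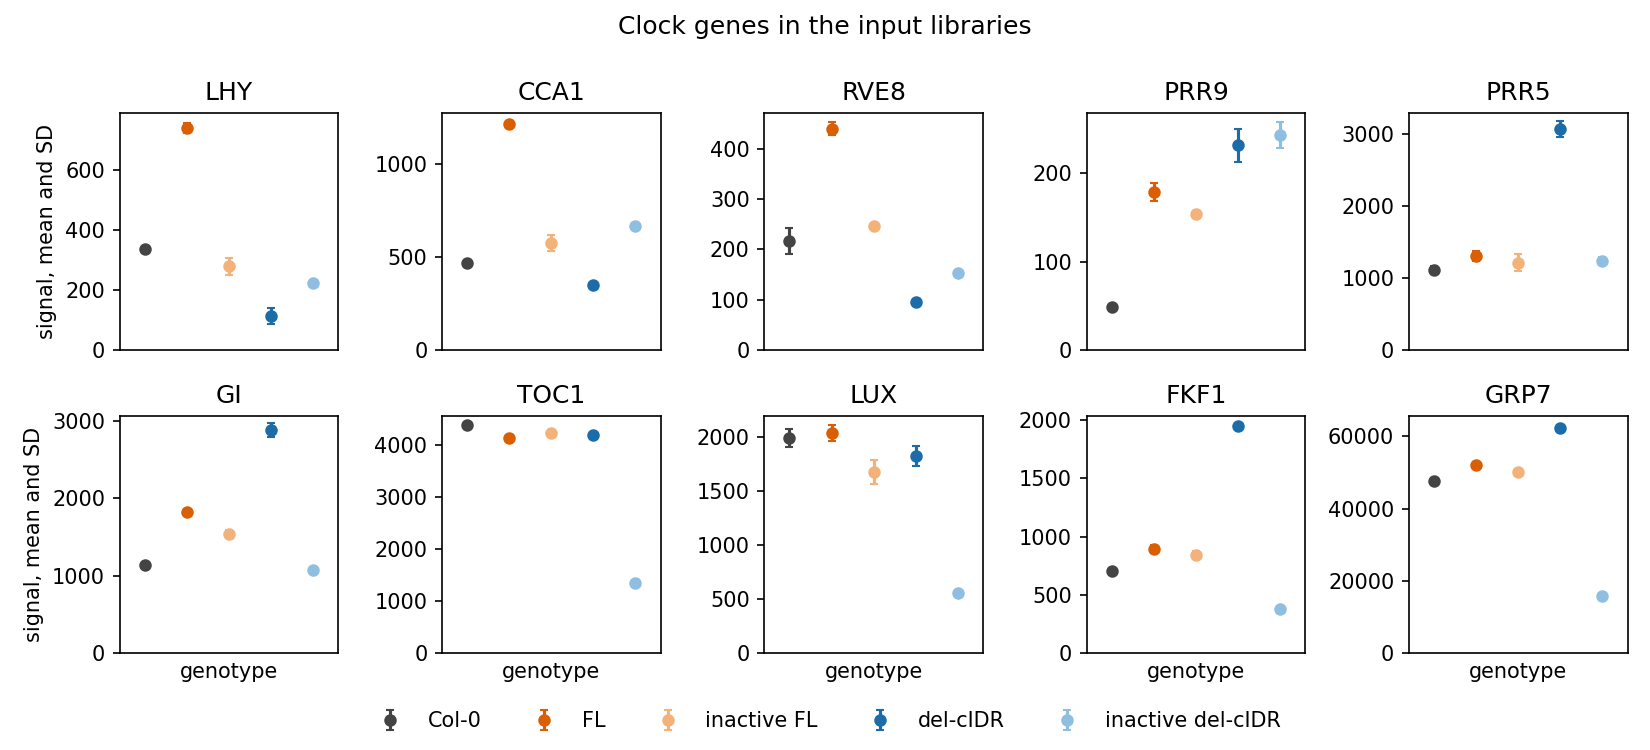
Signal of 10 clock genes in the input libraries of the 5 genotypes, mean and SD of 2 libraries, each panel with its own axis from 0. LHY and CCA1 are highest in FL, and TOC1, LUX, FKF1 and GRP7 are lowest in inactive del-cIDR, where GRP7 is at 15875.

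FL against inactive FL showed higher values of single morning clock genes and of all heat genes, but neither list differed from other features. On the clock list 8 of 16 genes rose and 0 fell (median 0.18, relative -0.25, camera adjusted p = 0.255), and the test turned negative after median-centring (0.0211). LHY had 739 ± 16.5 against 279 ± 28.7 (log2 fold change 1.38, relative 0.96, adjusted p = 9.03e-15), CCA1 1214 ± 14.9 against 577 ± 42.6 (1.06, relative 0.64) and RVE8 0.82 (relative 0.39). All 10 heat genes rose (median 0.91, relative 0.49), among them the chaperone genes HSP70-4 (280 ± 0.664 against 164 ± 26.8, 0.76, relative 0.33), HSP90.1 (0.61, relative 0.18) and HSP17.6A (1.27, relative 0.84), without a difference of the list from other features (camera adjusted p = 0.162). WRKY33, a defence transcription factor, had 5383 ± 124 against 3547 ± 216 (0.60, relative 0.17), WRKY70 1.02 (relative 0.59), and JAZ1, a jasmonate repressor gene, 0.82 (relative 0.40). The cold factor CBF2 had 986 ± 13.6 against 573 ± 38.8 (0.78, relative 0.35), in a list with 6 of 14 higher and 3 lower (0.162). XTR6, a cell-wall xyloglucan gene, had 714 ± 2.0 against 227 ± 31.1 (1.63, relative 1.2), and the other names of the rule were AT2G20142, AT3G00660, AT3G00650, AT2G10330, AT2G08986 and the transposable elements AT5TE40480, AT3TE58960, AT1TE43355, AT4TE19755 and AT5TE43520, from 1.72 to 1.58. The element AT3TE58605 (4.68) had an SD of 40825 around 29055 in FL.

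Photosynthesis genes did not share the rise of the median in FL against inactive FL. Of 25 genes 6 fell, 0 rose and most were not called (4 fell adjusted over the list alone). The list was lower than other features (median -0.05, relative -0.47, camera adjusted p = 6.23e-20, and 0.317 with an estimated correlation). In the highest of 10 classes of Col-0 level, the median rise of all features was 0.20. The list was not compared with features of like level. PSBP1, a photosystem II subunit, was at -0.17 (relative -0.60) and RBCS2B at -0.21 (relative -0.64). Of 132 plastid-encoded genes 55 fell and 13 rose (relative median -0.54, camera adjusted p = 5.68e-88; adjusted p = 0.101 with an estimated correlation), with ATCG00290 (-0.52), ATCG00110 (-0.49) and ATCG00700 (16267 ± 250 against 22600 ± 316, -0.47, relative -0.90) among the lower names of the rule. The nuclear ones were AT2G41190 (-0.82), AT2G01021, AT3G62950, MEE13, AT1G78995, OZF1, BGLU18, AT2G21530 and AT2G07741. On further lists 9 of 10 DNA methylation and silencing genes (camera adjusted p = 0.871), 8 of 8 histone methylation genes (0.122), 5 of 7 root hair and uptake genes (0.665) and 4 of 5 xylem genes (0.399) rose and 0 fell; the list tests of the first pair turned negative after median-centring (0.21 and 0.138). In all, limma called 17790 features higher and 230 lower (median 0.43), against 2279 and 7885 after median-centring, so the direction of the split turned. The count was 11913 without FL replicate 2 and 9347 without inactive FL replicate 1.

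Comparing the active forms, del-cIDR against FL, photosynthesis and organelle transcripts were higher in the del-cIDR line. These are separate lines, so the difference need not come from the missing region. Plastid-encoded transcripts also took a larger share in inactive del-cIDR (36.8% and 36.7%) than in inactive FL (27.2% and 26.5%). LHCB1.2 had 27036 ± 184 in del-cIDR and 12473 ± 18.8 in FL (log2 fold change 1.12, relative 1.26, adjusted p = 2.5e-31), LHCA1 1.04 (relative 1.18) and RBCS3B 1.36 (relative 1.50). In total 24 of 25 photosynthesis genes rose and 0 fell (24 and 1 adjusted over the list alone; camera adjusted p = 7.03e-67; adjusted p = 0.018 with an estimated correlation). Of 132 plastid-encoded genes 124 rose (4.76e-147; adjusted p = 0.0161 with an estimated correlation), ATCG00280 from 127820 ± 353 to 301880 (1.24, relative 1.38). Of 14 mitochondria-encoded genes 11 rose (3.62e-15; adjusted p = 0.00727 with an estimated correlation). Nuclear-encoded ribosomal protein genes rose in 28 of 65 (1.84e-11; adjusted p = 0.313 with an estimated correlation), with RPS1 at 0.81 and RPL15 at 0.59. LHY (115 ± 26.5 against 739 ± 16.5, -2.63, relative -2.49), RVE8 (-2.12) and CCA1 (352 ± 14.0 against 1214 ± 14.9, -1.77) were lower and PRR5 higher (3070 ± 115 against 1304 ± 66.6, 1.23), so that 5 of 16 clock genes rose and 7 fell (camera adjusted p = 0.825). Of 14 cold and ABA genes 9 rose and 3 fell (0.000268; adjusted p = 0.314 with an estimated correlation), RD29A by 1.06 and COR15A by 1.34. Heat genes fell in 6 of 10 (0.0504), jasmonate genes in 5 of 9 with 2 higher (0.155), JAZ1 by -1.0 and JAZ10 by -1.22. On the DNA methylation and silencing list 3 of 10 genes rose (0.0205; adjusted p = 0.432 with an estimated correlation), MET1, the maintenance DNA methyltransferase, by 0.42. Among the names of the rule AT5TE37665 (3.66), AT5G28335 (3.10), AT3G57420 (2.24), AT1G67105, AT4G04865, AT4TE10345, AT1G56300, AT4G04410, AT4TE10320, AT4G02825 and AT2G43590 were higher. AT1TE70175 (-2.33), AT1G56660, AT1TE73330, AT5TE11225, AT3TE39470, MDHAR and AT5G52020 were lower, as were AT3TE58605 (-4.92) and AT3TE58160 (-4.88), whose SD in FL were 40825 and 1756. limma called 3231 features higher and 6108 lower (median -0.14), and 8071 and 3354 after median-centring, which turned the split. The count was 6118 and 5738 without FL replicates 1 and 2 and 5843 without del-cIDR replicate 1.

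Against Col-0, FL had higher defence, jasmonate and cold transcripts. SRO5, a stress-response gene, had 603 ± 1.59 against 46.1 ± 1.46 (log2 fold change 3.52, relative 2.86, adjusted p = 2.29e-36), WRKY53 268 ± 7.16 against 23.7 ± 7.05 (3.18, relative 2.52) and WRKY33 5383 ± 124 against 890 ± 39.9 (2.59, relative 1.92). The lipoxygenase gene LOX4 had 2598 ± 44.8 against 291 ± 26 (3.13, relative 2.46) and CBF2 986 ± 13.6 against 150 ± 28.0 (2.67, relative 2.01). Of the immune list 12 of 14 genes rose (camera adjusted p = 0.000929), of the cold and ABA list 11 of 14 (0.000188) and of the jasmonate list 6 of 9 with 1 lower (0.034), each with adjusted p = 0.343 with an estimated correlation. LOX3 (2.51, relative 1.84) and JAZ1 (2.12, relative 1.45) led the last. CCA1 (1.37, relative 0.70) and PRR9 (1.74, relative 1.07) rose, with 12 of 16 clock genes (0.372). BPS3, AT3G00330, AT2G25460, AT1G50750, CYP94B3, XTH18, AT1G56660 and AT5G41750 lay between 3.55 and 2.96, and AT3TE58160 at 4.81 with an SD of 1756. AT3G01345 was the lowest (-2.66, relative -3.32).

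Organelle transcripts fell in the same comparison: 77 of 132 plastid-encoded genes with 10 higher (median -0.20, relative -0.87, camera adjusted p = 2.77e-105; adjusted p = 0.0341 with an estimated correlation) and 8 of 14 mitochondria-encoded genes (5.48e-18; adjusted p = 0.00465 with an estimated correlation). ATCG00970 was at -1.23 (relative -1.89), ATCG00920 at -1.0 and ATMG00180 at -0.66. ATCG01300, ATCG01240, ATCG01230 and the chromosome 2 loci AT2G07707, AT2G07741, AT2G07698, AT2G07725, AT2G07641 and AT2G07727 completed the lower names, to -0.81. Of 65 ribosomal protein genes 14 rose and 2 fell, while the list test was negative (4.64e-09; adjusted p = 0.343 with an estimated correlation) because it compares with the other features. Photosynthesis genes split, 14 of 25 higher and 6 lower (0.901), with LHCB1.1 at 1.36 (relative 0.70). All 10 heat genes rose (0.484), HSP18.2 by 1.54 and HSFA2 by 1.61. So did 7 of 7 genes of dividing cells (0.873), 8 of 10 of DNA methylation and silencing (0.664), 7 of 8 of histone methylation (0.404), 7 writers (0.751), 4 erasers (0.509), and 10 readers (0.873). Rising genes also numbered 6 of 9 flowering genes (0.536), 6 of 7 root hair and uptake genes (0.814), 3 of 4 endodermis genes (0.873), 4 of 5 xylem genes (0.419) and 4 of 8 seed storage genes with 1 lower (0.0551). The tests for readers, flowering, endodermis and seed storage were negative against positive medians. After median-centring the tests of the writers, erasers, photosynthesis, clock, DNA methylation and histone methylation lists turned negative. limma called 23127 features higher and 449 lower (median 0.67), and 4798 and 11914 after median-centring, which turned the split.

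del-cIDR against Col-0 showed higher cold, defence and photosynthesis transcripts, lists that camera also called higher in both inactive lines against Col-0. Of those calls in the inactive lines, only photosynthesis in inactive del-cIDR held with an estimated correlation. In inactive FL most immune genes were not called higher singly. CBF3 had 228 ± 22.3 against 14.2 ± 1.67 (log2 fold change 3.47, relative 2.92, adjusted p = 3.85e-22), CBF2 1218 ± 2.72 against 150 ± 28.0 (2.98, relative 2.42) and RD29A 1.92 (relative 1.36). FBS1 had 3.27, SRO5 2.91, BPS3 2.95, WRKY33 2.21 (relative 1.65) and LOX3 2.01 (relative 1.45). AT5TE37665 (338 ± 18.1 against 4.85 ± 1.80, 4.88, relative 4.32) and AT5G28335 (4.71, relative 4.16) rose most, with AT1G67105, AT3G00330, AT5TE31020, AT1G05675 and AT5G24915 at 3.57 to 2.90. LHCB1.1 had 24641 ± 70.4 against 5310 ± 125 (2.21, relative 1.66) and LHCB3 2.17. The photosynthesis list had 23 of 25 higher and 1 lower (camera adjusted p = 6.36e-44; adjusted p = 0.133 with an estimated correlation), cold and ABA 12 of 14 with 1 lower (2.7e-10; adjusted p = 0.145 with an estimated correlation). The immune list had 11 of 14 higher (0.00309), jasmonate 6 of 9 (0.0227) and DNA methylation and silencing 9 of 10 (0.0162), these 3 with adjusted p = 0.461 with an estimated correlation. Plastid-encoded genes had 118 of 132 higher with 7 lower (2.24e-29; adjusted p = 0.282 with an estimated correlation). On the clock list 7 rose and 5 fell (0.151), with GI (1.34, relative 0.78) and PRR5 (1.46, relative 0.90) higher, and LHY (115 ± 26.5 against 338 ± 3.02, -1.52, relative -2.08), RVE2 (-1.93) and JMJD5, a clock-associated demethylase gene (-1.39), lower. Other lower names were AT3G01345 (-3.91, relative -4.47), AT1TE73330, AT4TE83085, AT4TE34565, ARP9, THA1, AT1G62480, GLYI7 and AT1G64500, to -1.16. limma called 20054 features higher and 567 lower (median 0.56), and 2488 and 6458 after median-centring, which turned the split.

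Inactive lines also differed from Col-0 in expression. In inactive FL limma called 5173 features higher and 955 lower (median 0.22; 1527 and 5442 after median-centring, which turned the split), 3497 in total without Col-0 replicate 2 and 3811 without inactive FL replicate 2. Cold and ABA genes rose in 12 of 14 (camera adjusted p = 9.43e-15; adjusted p = 0.068 with an estimated correlation). Higher were also immune genes in 6 of 14 (2.97e-05) and photosynthesis genes in 15 of 25 with 1 lower (2.31e-11), both 0.237 as adjusted p with an estimated correlation, and jasmonate genes in 5 of 9 (7.13e-06; adjusted p = 0.12 with an estimated correlation). Plastid-encoded genes fell in 33 of 132 with 10 higher (3.33e-20) and ribosomal protein genes in 15 of 65 (3.28e-12), again both with adjusted p = 0.237 with an estimated correlation. Mitochondria-encoded genes fell in 9 of 14 (7.39e-17; adjusted p = 0.00545 with an estimated correlation). In inactive del-cIDR limma called 9920 features higher and 2400 lower (median 0.31; 3431 and 7548 after median-centring, which turned the split). All 25 photosynthesis genes rose (2.67e-59) and 8 of 9 jasmonate genes (1.17e-10), both with adjusted p = 0.044 with an estimated correlation. In contrast 11 of 16 clock genes fell and 4 rose (2.55e-13; adjusted p = 0.0725 with an estimated correlation). Cold and ABA genes rose in 10 of 14 with 1 lower (2.74e-07; adjusted p = 0.148 with an estimated correlation). Immune genes rose in 10 of 14 (3.4e-05; adjusted p = 0.184 with an estimated correlation), and dividing-cell genes in 7 of 7 (0.0235; adjusted p = 0.184 with an estimated correlation). Readers had 1 higher and 3 lower (0.00222) and writers 1 higher and 2 lower (0.0208), both with adjusted p = 0.196 with an estimated correlation. DNA methylation and silencing genes rose in 8 of 10 (0.0331; adjusted p = 0.336 with an estimated correlation), xylem genes in 5 of 5 (0.0303; adjusted p = 0.214 with an estimated correlation) and plastid-encoded genes in 83 of 132 with 10 lower (3.56e-07; adjusted p = 0.336 with an estimated correlation). Mitochondria-encoded genes had 4 higher and 6 lower, with a negative test and median (-0.10) against a mean of 0.12 (0.0416; adjusted p = 0.184 with an estimated correlation).

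Averaged over both forms, the active lines differed from the inactive ones by a median of 0.37, with 20401 features higher and 410 lower by limma, and 1168 and 4206 after median-centring, which turned the split. Photosynthesis genes fell in 21 of 25 with 1 higher (camera adjusted p = 1.24e-84) and jasmonate genes in 5 of 9 with 1 higher (1.68e-13), both with adjusted p = 0.0256 with an estimated correlation. Clock genes rose in 12 of 16 (1.51e-13; adjusted p = 0.07 with an estimated correlation). So did 8 of 8 writers (0.00321), 7 of 8 histone methylation genes (0.0112) and 12 of 14 mitochondria-encoded genes (0.0357), these 3 with adjusted p = 0.165 with an estimated correlation; the tests of the last pair turned negative after median-centring (0.623 and 0.145). Plastid-encoded genes had 63 higher and 12 lower, with a negative list test against a median of 0.10 (5.59e-05; adjusted p = 0.712 with an estimated correlation).

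Genes whose m6A peak fell against Col-0 differed little in expression from other genes with a peak. The median expression change was 0.34 for 411 genes with a lower peak in FL against Col-0 and 0.29 for 1562 others (permutation test over genes, two-sided, difference 0.05, p = 0.0019, adjusted p = 0.0086 over 32 tests). In inactive del-cIDR the difference was 0.07 (p = 0.00138, adjusted 0.00736), in inactive FL 0.00 (p = 0.819, adjusted 0.845), and in del-cIDR against Col-0 -0.02 (p = 0.415, adjusted 0.604, permutation test). Between del-cIDR and FL 9 genes with a lower peak had -0.12 and 1964 others 0.05 (p = 0.0721, adjusted 0.165, permutation test). These permutation tests, and those below, permute genes that were all measured in the same libraries. Their p-values do not measure the spread between libraries or lines. If the m6A ratio has the input as its denominator, part of such a relation is arithmetic. A check that pairs different replicate numbers leaves 1 library per group. Smaller differences in it can also come from having fewer libraries, so they do not show that the relation is arithmetic. Taking IP and input from libraries of different replicate number, the 20% of lowest and the 20% of highest m6A changes in FL against Col-0 differed by 0.01 (adjusted p = 0.845) and 0.03 (adjusted p = 0.2, permutation tests), against 0.08 (p = 1e-05, the smallest that the permutations can give) for all libraries. With all libraries the same comparison passed with 0.08 in del-cIDR against inactive del-cIDR (adjusted p = 0.00016), 0.04 in FL against inactive FL (0.00358) and in active against inactive (0.00358), 0.04 and 0.08 in inactive FL (0.0283) and inactive del-cIDR (0.017) against Col-0, and 0.08 in the interaction (0.00117). It did not pass in del-cIDR against FL (-0.04, 0.174) or against Col-0 (0.02, 0.74). Of the 18 comparisons with different replicate numbers 4 passed, with signs both ways. These were -0.09 in del-cIDR against Col-0 (adjusted p = 0.0086), -0.06 in del-cIDR against FL (0.015), 0.09 in the interaction (0.00992) and 0.06 in del-cIDR against inactive del-cIDR (0.0364). The other pairing of numbers gave -0.01 (0.845), -0.03 (0.408), 0.00 (0.845) and 0.02 (0.739) for these, by permutation tests.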

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

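The tests of scale, background, selection, genomic DNA and peak level below were chosen after the results were seen; those of the clock and of other splits of the libraries were chosen before, but the count of splits that keep genotypes together was added after.

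The difference between active and inactive lines was not the same in the del-cIDR and the full-length form, by a test of the difference itself. In m6A limma called 0 peaks higher and 4 lower for this difference (150 at unadjusted p under 0.05; median -0.51), named after their values were seen. They lay on AT2G05295 (-2.22, adjusted p = 9.04e-09, listed at 0 in both del-cIDR libraries), on SNC1 (-1.12, 0.0205) and, in no gene, at chromosome 3, 13209333 to 13209559 (-1.88, 0.00633, also at 0 in both del-cIDR libraries) and chromosome 5, 11731004 to 11731204 (-2.27, 0.0311). The count was 2 without Col-0 replicate 1 or del-cIDR replicate 2, 43 without FL replicate 1, 1 without inactive FL replicate 2, del-cIDR replicate 1 or inactive del-cIDR replicate 2, and 0 after median-centring. The photosynthesis peaks differed as a list (median -0.54, camera adjusted p = 0.000998; adjusted p = 0.935 with an estimated correlation and 0.876 after median-centring). The 217 other peaks in the lowest of 10 classes of Col-0 level had a median of -0.43. The 13 list peaks of that class did not differ from these by a permutation test over peaks (-0.11, adjusted p = 0.5). This does not show that they are equal.

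In expression 6146 features differed in this way, 1882 higher and 4264 lower (median -0.19; 6378 and 2112 after median-centring, which turned the split). Photosynthesis genes (camera adjusted p = 7.37e-18), jasmonate genes (5.24e-11), heat genes (0.0129) and immune genes (0.0431) were lower in the difference. Clock genes (1.64e-13), plastid-encoded genes (2.49e-55), mitochondria-encoded genes (0.000589), guard cell genes (0.0209), cold and ABA genes (0.0384) and writers (0.049) were higher. With an estimated correlation none of these calls held, with adjusted p = 0.145 for photosynthesis and guard cell, 0.0656 for jasmonate, clock, plastid and mitochondria, 0.258 for heat, 0.449 for immune, 0.437 for cold and ABA, and 0.3 for writers.

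The first pattern weighed is that m6A values were lower in all 4 lines than in Col-0, in the inactive lines too. Chance selection of peaks high in Col-0 would place the loss in thinly covered peaks, but in the fifth of peaks with the highest host gene input the median log2 ratio was -1.23. This speaks only to chance in thin coverage, since host gene input does not measure how peaks were selected. The 1st percentile of the peak values was 2.52 and 2.4 in Col-0, against 0.102 to 0.581 in the transgenic libraries. Selection of peaks through Col-0 could therefore not be set aside. A scale factor per library alone would give 1 log2 ratio at all levels, but the ratio of the active groups to Col-0 went from -2.49 in the lowest to -0.99 in the highest of 10 classes of peak level in the inactive groups, a difference of 1.5. A constant background in Col-0 alone would give 1 difference at all levels, but its largest median was 3.04 times its smallest. These 2 tests replaced earlier ones across 5 classes of host gene input, after those had been seen to give 0.11 and 1.23, values that met the bounds set for a scale factor and for a background; the Col-0 median ranged from 5.74 to 7.55 over those classes, against 3.26 to 17.1 over the new ones, and the new bounds were set after. A mix of scale, background and selection of peaks through Col-0 could not be separated from a loss of m6A caused by the transgene in these data. No biological explanation was tested.

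The second pattern is that weakly expressed features were higher in FL than in inactive FL inputs. A scale factor alone was excluded, since the lowest and highest of 10 classes of Col-0 level differed by 0.52. Genomic DNA should add signal with gene length, but silent genes over 4 kb gained at most 1.53 times as much as those of 0.5 to 1 kb, for lengths 5.57 to 6.66 times as large. This test replaced one on 6 class medians of gain per kb, which had given 2.67, and 1.36 without lncRNA genes; the latter met the bound set for genomic DNA, and the new bounds were set after. A nearly constant amount added to each feature by the normalization may contribute, but the largest gain over 5 length classes was 1.76 times the smallest, between the bounds set, so it cannot be told apart from a rise of silent transcripts.

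The third pattern is the difference of clock genes between genotypes. If seedlings were collected at different times of day, other rhythmic genes should move too. In inactive del-cIDR against Col-0 the median was 1.06 for 6 morning and midday genes and 0.03 for 6 evening genes outside the clock list. The difference, 1.02 (exact permutation p = 0.0563 over 924 assignments), was above the bound of 0.5 set for this explanation. The evening genes did not fall as a set: PRR3 (-1.43) and CAT3 (-1.01) fell, while CKB4 (0.27) and DPE2 (0.72) rose. The same difference was -1.18 in del-cIDR against inactive del-cIDR, 0.46 in FL against inactive FL and -0.81 in del-cIDR against FL (exact permutation p = 0.013 for each), and 0.62 in FL against Col-0 (0.026). In del-cIDR against Col-0 it was -0.36 (exact permutation p = 0.489), although LHY (-1.52) and PRR5 (1.46) moved, and in inactive FL against Col-0 0.17 (0.271). Collection at different times may therefore account for the clock pattern of inactive del-cIDR, while these 2 comparisons, and FL against inactive FL, do not reach the bound in size. An effect of the transgenes on the clock predicts the same and was not tested. The permutation tests of morning against evening genes permute genes, all measured in the same libraries. Their p-values do not measure the spread between seedlings or lines.

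Other splits of the 8 transgenic libraries into 4 and 4 were compared with active against inactive. Each side was fitted as 1 mean over its 4 libraries, with Col-0 as a separate group in the same fit. In expression the real split called 10151 features and the highest of the others 1420, and 1 of 35 splits called as many. Only 3 of the 35 keep the libraries of each genotype together. The splits that part the libraries of a genotype place the difference between genotypes in the residual spread and called at most 1. The bound set for this test was therefore wrong. The 3 that keep genotypes together do so in part, since each side pools genotypes. With 3 splits a share under 0.05 cannot be reached. In m6A the real split called 1 peak and 13 of 35 splits called as many, among them all 3 that keep genotypes together, so chance cannot be excluded. The highest of the others called 1055 peaks, with FL replicate 1, both del-cIDR libraries and inactive del-cIDR replicate 1 against the rest. These have the lowest m6A medians of the 8 (2.23, 2.63, 1.67 and 2.51, against 2.97 or more). This split goes with the order of the library medians and not with activity. Whether a shift of whole libraries gave the count was not tested.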

How the results depend on the processing

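Floor alignment was chosen after seeing the data; all other alternatives were chosen before. The number of called features stayed within 1.5 times its value for all 18 contrasts under robust moderation. Without the filter all 20 results, with the library medians, were the same by construction, since the filter had removed no feature. The count tools and the m6A value minus expression were not run, the former because the values are not counts and the latter because the m6A values are ratios whose denominator is not stated. Median-centring and quantile normalization fix the library medians and so give no value for their comparison. Causes were not tested except where the construction of an alternative is named.

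Removing a shift of whole libraries changed the results most. After median-centring m6A counts were 0 for all contrasts except del-cIDR against Col-0, which had 3. After quantile normalization they were 0 except for 5 in that contrast. Both remove by construction the shift common to the peaks. Expression counts after median-centring were 4708 for del-cIDR against inactive del-cIDR. With the split of higher and lower turned they were 10164 for FL against inactive FL, 11425 for del-cIDR against FL, 16712 for FL against Col-0, 8946 for del-cIDR against Col-0, 6969 for inactive FL against Col-0, 10979 for inactive del-cIDR against Col-0, 8490 for the interaction and 5374 for active against inactive. After quantile normalization the same contrasts had 5796, 5170, 10081, 11085, 7264, 4576, 9705, 6640 and 5239, with the split turned in all but the first.

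Of the genes and peaks named in the text, some turned against Col-0. The peaks on SVP (0.26) and SWN (0.21) turned in del-cIDR after median-centring, and after quantile normalization SVP (0.28), SWN (0.18) and GRP7 (0.13). The GRP7 peak turned in FL too, to 0.12 after quantile normalization.

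The stricter filter, which tests fewer features, left 0 peaks in all m6A contrasts except del-cIDR against Col-0 (710). It left 9696 expression features for FL against inactive FL, 11305 for FL and 11723 for del-cIDR against Col-0, and 12076 for active against inactive. With a pseudocount 10 times larger the m6A counts were 0 for del-cIDR against inactive del-cIDR, 8 for FL against inactive FL, 9 for del-cIDR against FL, 942, 955 and 863 for FL, inactive FL and inactive del-cIDR against Col-0, and 1 for the interaction. With one 10 times smaller they were 11 for del-cIDR against inactive del-cIDR, and 266 and 292 for FL and inactive FL against Col-0. Floor alignment gave 0, 2 and 1 peaks for del-cIDR against inactive del-cIDR, FL against inactive FL and del-cIDR against FL, 8, 42, 19 and 19 for FL, del-cIDR, inactive FL and inactive del-cIDR against Col-0, and 0 for the interaction. Of those against Col-0, 2, 5, 3 and 4 were higher.

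Without a trend in the prior variance the m6A counts were 0 for both activity contrasts, del-cIDR against FL, the interaction and active against inactive, and 212 and 313 for FL and inactive FL against Col-0. Expression counts were 6202 for del-cIDR against FL, 2819 for inactive FL against Col-0 and 2706 for the interaction. With only the libraries of the groups compared, peaks numbered 2 for FL against inactive FL, 3 for del-cIDR against FL, 344 and 1664 for FL and inactive FL against Col-0 and 2 for the interaction. Requiring a log2 fold change of at least 1 left 1 peak for active against inactive, as did leaving out organelle-encoded genes. It left 515, 3789, 1198, 10162, 4291, 696, 2012, 2233 and 172 expression features in the order of contrasts given for median-centring, fewer by construction.

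The pairing of libraries by replicate number is not established. With a replicate block FL against inactive FL had 8 peaks, and 35 of 36 results stayed within 1.5 times their value. As a check, residuals of libraries that share a number correlated across genotype pairs by -0.23 to 0.35 in m6A (median 0.12) and -0.04 to 0.10 in expression (median 0.06).

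The number of lists called depended on the set test. With an estimated correlation it was 0 in the m6A contrasts, and in expression 2 for del-cIDR against inactive del-cIDR, 0 for FL against inactive FL, 3 for del-cIDR against FL, 2, 0, 1 and 2 for FL, del-cIDR, inactive FL and inactive del-cIDR against Col-0, 0 for the interaction and 2 for active against inactive. With fry, which tests whether genes move on balance and not against other genes, it was 0 for FL against inactive FL, del-cIDR against FL, the interaction and active against inactive in m6A, and 3, 5, 4 and 4 for FL, del-cIDR, inactive FL and inactive del-cIDR against Col-0. In expression fry gave 16 for del-cIDR against inactive del-cIDR, 19 for FL against inactive FL, 12 for del-cIDR against FL, 21, 21 and 11 for FL, del-cIDR and inactive FL against Col-0, and 21 for active against inactive. After median-centring camera called 1 m6A list for del-cIDR against inactive del-cIDR and 0 for del-cIDR against FL and the interaction, and in expression 3, 7 and 11 for del-cIDR against inactive del-cIDR, FL against inactive FL and FL against Col-0. Among lists called by the test as reported, those whose direction turned were ribosomal protein genes in FL against Col-0 (fry, 0.0353), readers in del-cIDR against Col-0 (fry, 0.0137), plastid-encoded genes in active against inactive (fry, 0.0378), and in the same contrast after median-centring histone methylation (0.623) and mitochondria-encoded genes (0.145).

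Leaving out each library in turn gave, for m6A, 0 to 41 peaks for del-cIDR against inactive del-cIDR, 2 to 16 for FL against inactive FL, 8 to 296 for del-cIDR against FL, 187 to 1590 for FL, 622 to 2037 for del-cIDR, 228 to 848 for inactive FL and 270 to 886 for inactive del-cIDR against Col-0, 1 to 43 for the interaction and 1 to 93 for active against inactive. Expression counts were 9347 to 18725 for FL against inactive FL, 5738 to 10245 for del-cIDR against FL and 3497 to 7146 for inactive FL against Col-0. The difference of m6A medians ranged from -0.84 to -0.43. The correlation of the 2 activity effects ranged from -0.02 to 0.22 and was 0.036 after quantile normalization. For m6A against expression, the 20% of lowest and of highest changes differed by 0.04 in inactive FL against Col-0 and passed where called peaks had not. Depth is unknown, so its limit on these counts could not be given.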

Other observations

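The 5th percentile of the m6A values was 3.25 and 2.97 in the Col-0 libraries and between 0.283 and 0.966 in the 8 transgenic libraries. In the input libraries the 5th percentile of the expression values was 3.89 and 3.42 in Col-0, 12.3 and 16.0 in FL, 5.27 and 7.91 in inactive FL, 8.82 and 12.1 in del-cIDR, and 6.47 and 7.98 in inactive del-cIDR. Transposable elements held 0.631% and 0.571% of the signal in Col-0 and 1.37% and 1.40% in FL. The most abundant feature held 24.6% to 32.9% of the signal of an input library.

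Against 10 classes of peak level, the Col-0 median lay on a line with an intercept of 1.90 and a slope of 1.77 when set against the active groups, and with 2.16 and 1.37 when set against the inactive groups. The median log2 change of expression between FL and inactive FL was 0.72 in the lowest and 0.20 in the highest of 10 classes of Col-0 level.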
